A study of Escherichia coli with 50 samples.

How the data were processed

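ChIP-exo was measured in 50 libraries of 9 TAP-tagged proteins of Escherichia coli strain DY330, each protein without shock and after a 6 min heat shock. The deposited files are peak lists, 1 per library, which name genetrack as the source of their peaks, per the file contents. The value of each deposited peak was taken as the count of tags on its strand, without normalization, because the values were whole numbers of at least 2 whose totals differed between libraries. Every peak but 1 of 4496345 spanned the same width. BWA, Picard and SAMtools are named in the submitters' processing notes, and their versions and the genome build are not given in the sources used here. Peaks were called separately in each library, and a peak with fewer than 2 tags was not listed. Totals are therefore tags in listed peaks, not the depth of the library, and ranged from 4214 to 2726977. The spread between libraries bounds the precision of each value, and no interval for counting error is given.

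The peaks reached position 4646330, beyond the last gene end at 4641628 in the gene table at hand, so the builds differ and no gene name, gene start, published site list or sequence motif was used. Tags were summed over both strands in 9293 bins of 500 bp, of which 232 held no tag in any library. This was the fallback written for such a case before the data were examined, as were the grouping, the tests, the rule for named bins and most alternatives. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

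Heat-shocked and unshocked libraries of a protein were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment, a bin being called at an adjusted p under 0.05. Each protein was fitted on its own libraries, compared in the same way with the MglB background, and RpoH's change was compared with that of RpoD, RpoA, RpoB and RpoC by an interaction term. The bins named are up to 10 of the largest rises and of the largest falls among the called bins in which every heat-shocked library lay above, or below, every unshocked one, and the 10 largest rises over MglB without shock. Bins named for the interactions, the subunits, the stretch with few tags and the sites were chosen after their values were seen. DESeq2 1.42.0, other library sizes, no filter, 1 fit over all libraries, a replicate block, thinning, a higher peak minimum, single library series and leaving out each library were tried as alternatives, and wider bins, a series term, leaving out shallow libraries, all 4 MglB libraries as the control, and every alternative for the interactions, the subunits, the site shares and the set tests were added after the data were examined. All tests were two-sided unless said otherwise.

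A set of sites was drawn for RpoH, RpoN, RpoD, Fis and HimD from unshocked libraries, by a rule set after the data were examined and after other definitions had been viewed: at least 50 tags in the bin in the deepest MglB library, a mean at least 2 times the CPM of that library (tags over the library's total in listed peaks, on the usual CPM scale), and in each unshocked library at least 10 tags and 2 times the median of the 21 bins around it. Shares of tags were compared with exact permutation tests adjusted over 45 comparisons, and set changes with the camera test of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2). Nearness of the calls to the sites was tested by rotating the sites along the chromosome 10000 times, one-sided for more calls near them. Overlap of the 1000 highest peaks used a tolerance of 10 bp. Peaks of opposite strands were paired within 100 bp for strand distances.

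Library scaling moved the median log2 change over bins by more than 0.1 in some comparisons. With total tags as the library size the shift from TMM was −0.171 in RpoH, −0.483 in RpoD, −0.192 in RpoN, −0.401 in RpoA, 0.16 in RpoB, 0.7 in RpoC and −0.112 in MglB, and with DESeq2 size factors 0.462 in RpoC and 0.487 in MglB. Replicates with the same number were checked for pairing by the correlation of their deviations from the group means. In RpoA all 3 pairs passed 0.1 (0.378, 0.313 and 0.121). Each RpoA replicate number is also its own library series (the leading digits of the library number), so the check cannot tell a pairing from the series. RpoD (0.166), MglB (0.503) and Fis, paired by series (0.219), passed it as well, each from 2 pairs that share 1 value. Values with the block are therefore given for RpoA where the block moved a count by over 1.5 times, and for Fis. In RpoD and MglB the block left the heat shock count at 0. The tests were tried on simulated data drawn from the means and sizes of the libraries with 200 bins changed. Summaries used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.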

Results

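The series profiled where 9 tagged proteins sat on the chromosome of Escherichia coli before and after a 6 min heat shock. The strain was DY330, a laboratory strain built for recombineering, grown in LB medium at 30 °C and fixed with 1.0% formaldehyde. Each protein carried a TAP tag, which binds IgG, and was captured for ChIP-exo, an assay in which an exonuclease trims the captured DNA up to the crosslinked protein so that each strand ends close to the site. RpoH, RpoD and RpoN are sigma factors, the subunits that bring RNA polymerase to promoters: RpoH serves heat shock promoters, RpoD the housekeeping promoters and RpoN promoters that need an activator protein. RpoA, RpoB and RpoC are subunits of the core polymerase. Fis and HimD, the beta subunit of integration host factor, are DNA-bending proteins of the nucleoid. MglB is a sugar-binding protein of the periplasm and served as the background. The labels give no temperature for the shock.

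The 50 libraries form 18 groups. RpoH and RpoC had 4 heat-shocked and 4 unshocked libraries each, RpoA, RpoB and HimD 3 of each, and RpoD, RpoN, Fis and MglB 2 of each. The files list peaks of at least 2 tags with their whole tag counts, so a bin with no listed tag can still have held single tags. Tags in listed peaks ranged from 4214 to 2726977 per library. The mean was lower after heat shock for each protein, by 1.62 times for RpoC, 2.04 for Fis, 2.44 for RpoB, 3.22 for HimD, 3.82 for RpoA, 4.0 for RpoD, 4.84 for RpoH, 11.8 for RpoN and 21.8 for MglB. The 2 MglB libraries of each condition were unequal, with 2726977 and 9756 tags without shock and 121305 and 4214 after it. Intervals and p-values given here cover the spread between these libraries. The labels do not say whether replicates came from separate cultures, so that spread may be technical. Positions are given on the coordinates of the files, whose build is not given in the sources used here, in bins of 500 bp on the single chromosome, and genes are therefore not named.

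**Figure D1:**
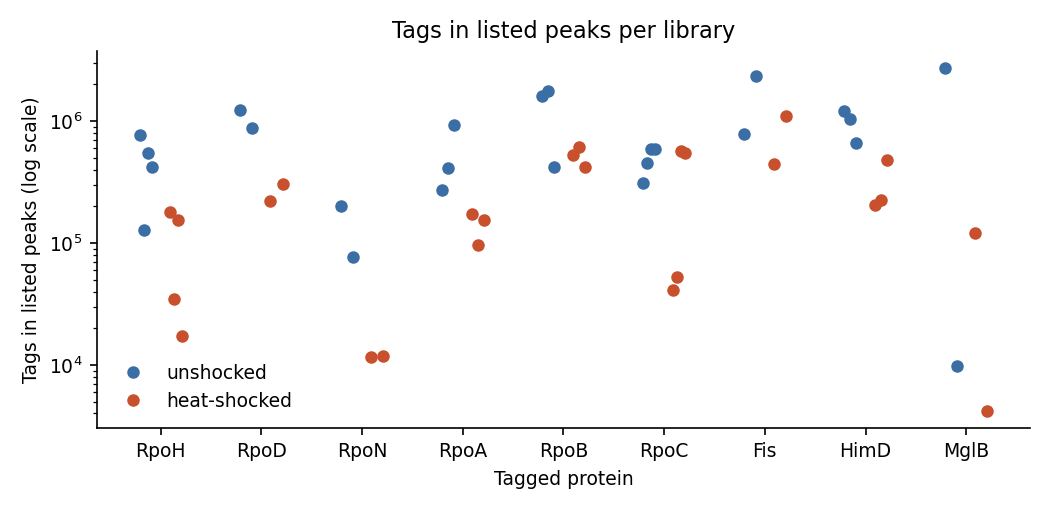
Tags in listed peaks (log axis) of each of the 50 libraries as points, by tagged protein and condition. The heat-shocked RpoN libraries hold 11516 and 11884 tags, and the 2 MglB libraries of each condition lie far apart.

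Among unshocked libraries Fis and HimD had the highest overlap of replicates at 1000 peaks and 10 bp, and other proteins were as high elsewhere, such as heat-shocked RpoD with 81.9% against 81.2% in HimD and unshocked RpoN with 84.2% among the 200 highest peaks against 80.5% in Fis. Of the 1000 highest peaks of an unshocked Fis library, 89.5% had a same-strand peak within 10 bp among the 1000 highest of its replicate, and 0.3% on average did in libraries of other proteins. For unshocked HimD the overlap was 84.0% against 0.7%, and for RpoN 69.0% against 2.9%. RpoH replicates shared 48.3% and libraries of other proteins 26.1%, and the MglB pair shared 7.6% against 13.1%. Peaks on opposite strands stood 31 to 32 bp apart in Fis, 29 to 31 bp in HimD and 30 to 32 bp in RpoN (medians per library over both conditions). In RpoN the most common distance was nonetheless 5 to 9 bp. The polymerase subunits gave shorter medians, 17 to 19 bp in RpoB, 18 to 21 bp in RpoA and 19 to 22 bp in RpoC. The deeper MglB library of each condition also had a median of 18 bp, and the shallower ones 43 and 30 bp. A short distance was thus not particular to the polymerase. RpoH libraries had 22 to 33 bp. No test was made of overlaps or distances.

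In the main setting Fis and HimD also rose above the MglB background over the most bins. Without shock, 2138 of 9040 tested bins were higher and 1674 lower in Fis (n = 2) than in MglB (n = 2), and 2591 were higher and 2221 lower of 8693 in HimD (n = 3), at an adjusted p under 0.05 in the edgeR quasi-likelihood test. The largest Fis rise was at 2182001 to 2182500, with 1832 ± 248 CPM (tags scaled to the same library total) (SD, n = 2) against 37.8 and 0 in the MglB libraries, a log2 change of 6.01 ± 1.35 (SE, adjusted p 8.5e-05). Fis bins at 3562501, 2410001 and 3146001 held 1810 ± 72.6, 1818 ± 160 and 1822 ± 177 CPM. The largest HimD rise was at 2782001 to 2782500, with 1624 ± 160 CPM (n = 3) against 29.7 and 0, a log2 change of 6.19 ± 0.67 (adjusted p 2.3e-06). HimD bins at 2776501 and 3268501 held 2634 ± 421 and 1411 ± 181. Leaving out 1 library moved the higher bins of Fis to 3232 without the shallow MglB replicate 2 and to 0 without either Fis replicate. Those of HimD became 0 without HimD replicate 1 and 657 without replicate 2. Against all 4 MglB libraries Fis had 0 higher bins, fewer than the 43 of RpoN, and HimD had 1655. DESeq2 called 635 higher bins in Fis and 1725 in HimD.

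The sigma factor RpoH stood above MglB at 289 of 9049 bins without shock and below it at 64 (n = 4 and 2). Its 5 largest rises were at 1864001, 693501, 4375001, 12001 and 4373001, with means of 4280 ± 5918, 2451 ± 2210, 2431 ± 2857, 2053 ± 1956 and 1595 ± 1793 CPM (SD, n = 4). The deeper MglB library held 106, 79.2, 101, 104 and 67.8 CPM there. RpoC was higher at 478 of 6430 bins and lower at 301, with 10618 ± 558 CPM at 3601001 and 10633 ± 1373 at 3654001 against 2944 and 3379 in the deeper MglB library (log2 3.34 ± 0.96 and 3.35 ± 0.96, SE). RpoA was higher at 5 of 8691 bins and lower at 3, the largest rise being 96.5 ± 42.8 CPM at 2772001 against 10.3. The edgeR test called 0 bins for RpoD, RpoN and RpoB, where 898 of 9038, 339 of 3786 and 154 of 9052 bins had an unadjusted p under 0.05 and DESeq2 called 304, 163 and 0 higher bins. In data simulated on these libraries the test recovered none of the 8-fold changes for RpoD, RpoN and RpoB over MglB, so a rise of that size was not detectable there.

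Those counts rest on the setting and on single libraries. DESeq2 called 7 higher bins for RpoH, and peaks of at least 5 tags or all 4 MglB libraries as the control gave 0. RpoC was higher at 152 and lower at 2218 bins with total tags as the library size, and at 0 and 22 against all 4 MglB libraries. The RpoH count became 0 without MglB replicate 1, 3 without RpoH replicate 1, 770 without replicate 2, 11 without replicate 3 and 4 without replicate 4, and the RpoC count 1718 and 1547 without MglB replicates 1 and 2 and 19, 6, 1 and 187 without RpoC replicates 1 to 4. The RpoA count became 184 without MglB replicate 2 and 0 without MglB replicate 1 or any RpoA replicate, the RpoD count 400 without MglB replicate 2, and the RpoN count 331 and 427 without MglB replicates 1 and 2. After heat shock the same comparison gave 8 higher and 0 lower bins for RpoH, 189 and 408 for RpoD, 90 and 105 for RpoN, 2278 and 843 for Fis and 1765 and 798 for HimD. It gave 0 in edgeR for RpoA, RpoB and RpoC, with 89, 853 and 12 bins at an unadjusted p under 0.05, and DESeq2 was not run on the heat-shocked comparison.

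RpoN tags were gathered at few places. The bin from 2849001 to 2849500 held 54279 ± 25608 CPM in unshocked RpoN libraries (SD, n = 2), against 98.6 ± 30.5 in RpoD (n = 2) and 65 ± 22.1 in RpoC (n = 4), and 114914 ± 43 in heat-shocked RpoN libraries. Next by fold over the deepest MglB library were 3434501 with 16932 ± 4186 and 33237 ± 953, and 4302501 with 10787 ± 2981 and 21082 ± 1255 CPM without and with shock. RpoC held 26.2 ± 16.5 and 5.31 ± 4.25 at those bins without shock. The tallest forward and reverse peaks at 3434501 lay at 3434926 to 3434927 and at 3434963 in the 4 RpoN libraries, 36 bp apart, and those at 2849001 lay 157 bp apart at 2849122 and 2849279. A rule set after the data were examined, at least 2-fold above the deepest MglB library and 2-fold above the local median in each unshocked library, gave 443 RpoN bins. These held 45.2% ± 11.5 of RpoN tags without shock and 69.0% ± 1.87 after it (exact permutation p = 0.333, the smallest that 2 against 2 can give; adjusted p = 0.75 over 45 tests). With each library thinned to the listed tags of the shallowest, the difference turned from 23.8 to −3.62 percentage points. In RpoC the same bins held 1.79% ± 0.18 of tags without shock and in MglB 3.82% ± 1.02.

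**Figure D2:**
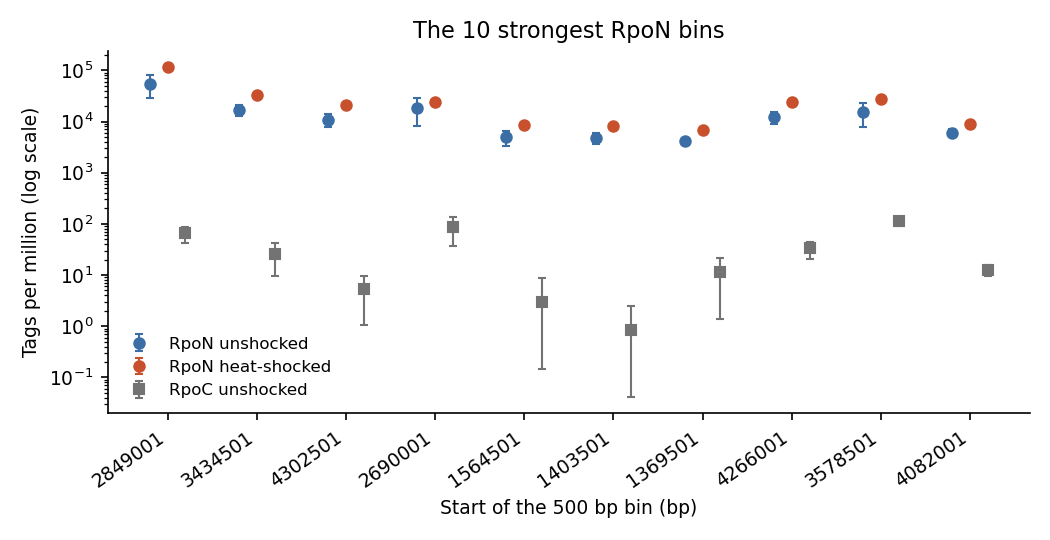
CPM (log axis) in unshocked and heat-shocked RpoN libraries and in unshocked RpoC libraries at the 10 RpoN bins with the largest ratio to the deepest MglB library, as group means with SD, where a lower bar that would reach 0 is shortened. RpoN lies far above RpoC at each of the 10, with 54279 and 114914 CPM at the first.

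After heat shock RpoH rose at 33 bins and fell at 4 of 6244 tested (edgeR, adjusted p under 0.05, n = 4 and 4). In 31 of the rises and all 4 falls no heat-shocked library overlapped an unshocked one. These bins were called on the same libraries, so the lack of overlap describes them and is no further support. The chance share of 0.0286 holds for bins not selected by the test. The largest rise was at 1445001 to 1445500, from 120 ± 44.6 to 1090 ± 685 CPM (log2 2.98 ± 0.43, SE, adjusted p 3.0e-06). At 1341501 RpoH rose from 371 ± 200 to 2584 ± 1272 (log2 2.67 ± 0.53), at 922001 from 238 ± 125 to 1415 ± 886 and at 3995001 from 643 ± 393 to 3561 ± 1656. Rises at 1914001, 1385501, 415001 and 3486001 had log2 changes of 2.29, 2.28, 2.21 and 2.10. The neighbouring bins 808501 and 809001 rose from 38.9 ± 16.2 to 266 ± 176 and from 35.6 ± 17.9 to 170 ± 90.5 CPM. At 808501 the deeper MglB pair also held more tags after heat shock, 997 against 45.8 CPM. Over all 33 RpoH rises that pair was higher at 14 and lower at 19, and at the 4 falls it was lower each time. The 4 falls were at 2709001, 2408001, 207001 and 1642501, with log2 changes of −2.96, −2.77, −2.61 and −1.84, and each had at most 3 or 4 of 16 other settings past the threshold.

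The RpoH count depended on single libraries and on the library series. It became 17, 75, 15 and 16 without unshocked replicates 1 to 4 and 20 without heat-shocked replicate 4, 101 in DESeq2, and 0 from peaks of at least 5 tags. Within the series numbered 17 the test called 0 of the bins and within series 21 it called 67, with 2 libraries per condition in each.

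The mean of RpoH was higher after heat shock at each of its 10 strongest unshocked sites. The rule described for RpoN gave 38 RpoH bins. Of these, 21 were also HimD bins, 17 RpoD bins, 12 Fis bins and 6 RpoN bins, where independent lists give 7.27, 3.79, 6.26 and 1.87. The 38 bins held 2.94% ± 2.39 of RpoH tags without shock and 8.50% ± 4.0 after it (SD, n = 4 and 4, exact permutation p = 0.0857, adjusted p = 0.75 over 45 tests). This difference of 5.56 points was within the spread of the libraries by this test. The ratio was 1.63 in series 17 and 7.31 in series 21. At 693501 to 694000 RpoH went from 2451 ± 2210 to 10479 ± 6063 CPM, at 3772501 from 1652 ± 1243 to 6765 ± 3781, at 494001 from 1661 ± 1562 to 6565 ± 3037 and at 12001 from 2053 ± 1956 to 7204 ± 3930. At 1864001 the values were 4280 ± 5918 and 5494 ± 2456. The tallest peaks at 693501 lay at 693865 to 693867 on the forward strand and at 693902 to 693905 on the reverse strand in all 8 libraries. In limma's camera test the 38 bins ranked higher than the other bins in the RpoH contrast (median log2 0.35 against −0.93 over all bins, 24 of 38 higher, adjusted p = 8.1e-21 with a preset correlation and adjusted p = 0.0224 with an estimated correlation). With an estimated correlation the adjusted p was 0.434 after thinning, 0.0998 with the replicate block, and 0.101 and 0.127 without heat-shocked RpoH replicates 2 and 4. The list was chosen on unshocked libraries that also enter this contrast, so its direction there is not independent evidence.

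All 3 polymerase subunits held a larger share of their tags at the 38 RpoH bins after heat shock. RpoC went from 0.404% ± 0.053 to 0.708% ± 0.136 (n = 4 and 4, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.75), RpoA from 0.685% ± 0.160 to 1.17% ± 0.118 and RpoB from 0.400% ± 0.030 to 0.793% ± 0.093 (n = 3 and 3, exact permutation p = 0.1 for both, the smallest possible). Within library series the ratios were 1.46, 1.96 and 1.80 in RpoA, 1.89 and 2.16 in RpoB and 1.5 and 2.04 in RpoC. From peaks of at least 5 tags the RpoC conditions overlapped, with 0.167% to 0.294% without shock and 0.0448% to 1.23% after it (exact permutation p = 0.4). RpoD went from 1.23% ± 0.427 to 0.952% ± 0.003, Fis from 1.05% ± 0.114 to 1.12% ± 0.158, HimD from 1.59% ± 0.126 to 1.57% ± 0.149, RpoN from 6.27% ± 2.56 to 12.8% ± 0.273 and MglB from 0.593% ± 0.335 to 0.790% ± 0.043. At 693501 RpoA, RpoB and RpoC went from 101 ± 33.8, 55.5 ± 7.37 and 53.2 ± 5.56 to 342 ± 119, 220 ± 70.3 and 209 ± 42.7 CPM, while RpoD held 31.4 ± 8.86 and 31.3 ± 6.93. The ratio of the RpoC shares was 1.60 at HimD, 1.47 at RpoN, 1.36 at Fis and 0.9 at RpoD bins (exact permutation p = 0.429, 0.4, 0.429 and 0.171), and after thinning 2.83, 2.10, 1.98 and 0.976 (exact permutation p = 0.0286, 0.0286, 0.0286 and 0.83, adjusted p = 0.321 for the first 3 and 1.0 for RpoD). Of the 38 RpoH bins, 21 were among the 1721 HimD bins, 6 among the 443 RpoN, 12 among the 1482 Fis and 17 among the 897 RpoD bins. Shared bins were thus a small part of those sets, and ratios without them were not computed. Whether the rise was particular to RpoH bins was not tested. At 12001 MglB moved too, from 51.9 ± 73.4 to 705 ± 997.

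**Figure D3:**
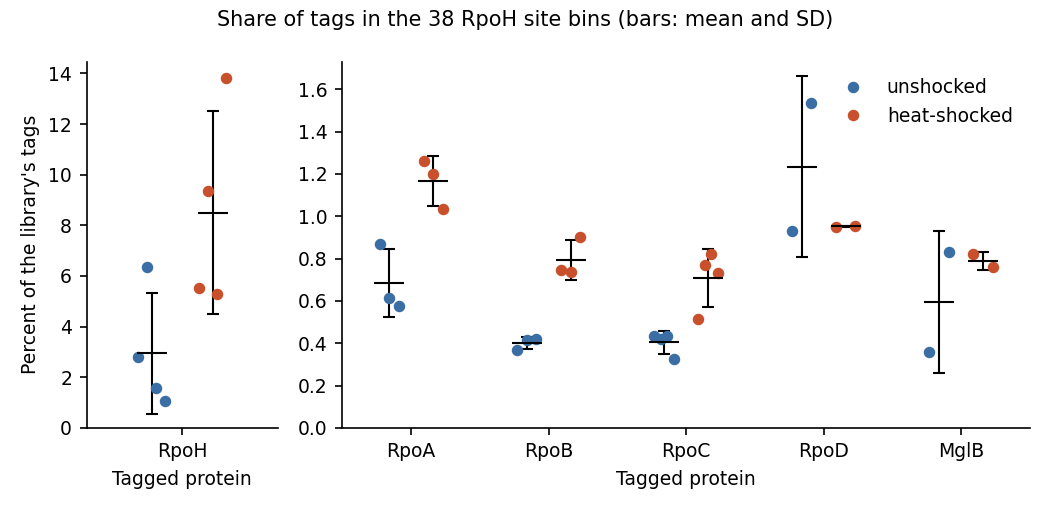
Percent of each library's tags in the 38 RpoH bins, for RpoH on the left axis and for RpoA, RpoB, RpoC, RpoD and MglB on the right one, with points for libraries and black bars for the mean and SD. Every heat-shocked RpoA, RpoB and RpoC library lies above every unshocked one of the same protein, and the RpoH, RpoD and MglB conditions overlap.

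Polymerase rises lay near the RpoH bins more often than rotations of those bins along the chromosome gave. Within 2 kb lay 29 of 65 RpoA rises (mean of 10000 rotations 2.32, one-sided permutation p = 0.0003), 9 of 20 RpoB rises (0.73, p = 0.0002) and 44 of 304 RpoC rises (10.9, p = 0.0001, the smallest possible; 1 rotation test per subunit and direction, 6 in all). For falls the numbers were 5 of 55 in RpoA, 2 of 17 in RpoB and 20 of 495 in RpoC (mean of rotations 2.03, 0.6 and 18.01). These also lay above the means, but within the spread of the rotations (one-sided permutation p = 0.147, 0.145 and 0.382). The limma camera test placed the 38 bins above the other bins in RpoA (median log2 0.51 against −0.26, adjusted p = 8.6e-11), RpoB (0.36 against 0.00, 9.8e-07) and RpoC (37 bins tested, −0.17 against −0.80, 2.0e-05). With an estimated correlation these calls were lost, the adjusted p being 0.150 in RpoA, 0.350 in RpoB and 0.0673 in RpoC. In RpoC the direction of the test was up while the median of the bins lay below 0. In RpoD the bins ranked higher too (0.27 against −0.15, 27 of 38 higher, adjusted p = 0.0142, and adjusted p = 0.793 with an estimated correlation).

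RpoA changed at runs of adjoining bins. It rose at 65 bins and fell at 55 of 4029 (edgeR, n = 3 and 3). Of these, 63 rises and 54 falls had no overlap between the conditions (chance share 0.1 for bins not selected by the test). The largest rise was at 3773001 to 3773500, from 80.6 ± 28 to 618 ± 139 CPM (log2 3.24 ± 0.40, adjusted p 0.00038). Then 4 adjoining bins from 12001 to 14000 rose, at 12001 from 161 ± 32.9 to 899 ± 189 and at 13501 from 67.6 ± 5.28 to 403 ± 120, and so did 3 bins from 4375501 to 4377000 (log2 2.84, 2.84 and 2.77). The deeper MglB pair rose at the same places, from 110 to 610 CPM at 3773001, from 104 to 1410 at 12001 and from 99.0 to 635 at 4375501. It was higher after heat shock at 60 of the 65 RpoA rises and lower at 53 of the 55 falls. RpoA fell at 2399001, 4327001, 1340001, 2402001, 133501 and 139501 from 155 ± 47.0, 154 ± 34.4, 84.6 ± 12.9, 84.4 ± 26.2, 76.3 ± 16.5 and 73.0 ± 10.9 CPM to no listed tag in any heat-shocked library. At 2398501, 2398001 and 2396501 it fell by 4.46, 4.34 and 4.25 on the log2 scale.

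The RpoA calls depended on tag numbers and on small peaks, with 31 rises and 13 falls in libraries thinned to equal tags in listed peaks and 9 rises and 55 falls from peaks of at least 5 tags. Falls to no listed tag were seen in libraries with 3.82 times fewer listed tags on average. The share of rises was 54.2%, and 37.9% (33 up, 54 down) with total tags as the library size. With the replicate number as a block, which passed the pairing check but coincides with the library series in RpoA, the test called 258 bins (141 up, 117 down). The 120 calls became 67, 15 and 17 without unshocked replicates 1 to 3, 239 without heat-shocked replicate 1 and 43 without heat-shocked replicate 3.

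RpoB rose at 20 bins and fell at 17 of 7055 (n = 3 and 3), each with no overlap between the conditions (chance share 0.1 for bins not selected by the test). The largest rise, at 808501 to 809000, went from 17.3 ± 9.16 to 570 ± 134 CPM (log2 5.04 ± 0.63, adjusted p 0.0139). RpoB rose at 3773501 from 37.8 ± 27.2 to 460 ± 141, at 13501 from 52.7 ± 37.4 to 611 ± 215, at 13001 from 61.1 ± 33.1 to 616 ± 178 and at 772001 from 40.5 ± 9.81 to 340 ± 42.8. It fell at 2309501 from 120 ± 6.82 to 11 ± 6.84 (log2 −3.72 ± 0.46), at 446001 from 146 ± 46.8 to 19.4 ± 5.99 and at 7 of the 10 named falls between 2400001 and 2406000, from 81.3 to 123 down to 12.6 to 20.9 CPM. The deeper MglB pair was higher after heat shock at 17 of the 20 rises and lower at all 17 falls. Over the bins tested in all 3 subunits it was higher at 32.4% and lower at 67.6%. With total tags as the library size 81.1% of calls were rises (60 up, 14 down) against 54.1%. Rises also outnumbered falls in thinned libraries (29 up, 11 down), with a series term (27 up, 11 down) and with DESeq2 size factors (19 up, 13 down). They did not in 1 fit over all libraries, with 262 calls (87 up, 175 down). Nor did they with the replicate block, at 229 calls (109 up, 120 down), or in DESeq2, at 134 (67 up, 67 down). The main count became 58 without unshocked replicate 3 and 0, 14 and 1 without heat-shocked replicates 1 to 3, and 0 within series 17, with 2 libraries per condition.

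RpoC had the most calls of the 9 proteins, 304 rises and 495 falls of 4646 bins (n = 4 and 4). Of its 10 largest rises 8 lay on the 2 sides of a stretch with almost no tags in any library, from 793001 to 806000. At 808501 RpoC rose from 3.37 ± 3.89 to 748 ± 396 CPM (log2 6.95 ± 0.49, adjusted p 2.3e-41), at 809001 from 1.94 ± 2.27 to 302 ± 152, at 791001 from 2.44 ± 3.07 to 172 ± 63.8 and at 790001 from 4.63 ± 3.79 to 212 ± 112. It rose at 181001 from 4.97 ± 6.31 to 128 ± 22.5 and at 4364001 from 4.47 ± 3.18 to 105 ± 38.7. Of its 10 largest falls 7 lay from 446001 to 451000, at 446001 from 223 ± 35.8 to 21.5 ± 25.1 (log2 −3.14 ± 0.34) and at 449501 from 359 ± 49.5 to 66.4 ± 44.7, and at 4187501 and 4188001, from 837 ± 100.5 to 178 ± 58.3 and from 934 ± 105 to 190 ± 37.0, and at 2309501, from 120 ± 34.9 to 14.3 ± 17.3.

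For RpoC, 109 rises and 196 falls had no overlap between the conditions (chance share 0.0286 for bins not selected by the test). The deeper MglB pair was higher after heat shock at 161 of the 304 rises and lower at 143. At the 495 falls it was lower at 393 and higher at 102. All 304 rises were separated within series 21 and 119 within series 20. The split depended on the scaling, with 38% of calls up in the TMM scaling, 73% (336 up, 124 down) with DESeq2 size factors and 84.1% (334 up, 63 down) with total tags, while no named bin turned its direction. Thinned to the listed tags of the shallowest library, RpoC had 86 calls (52 up, 34 down), and from peaks of at least 5 tags 24 (5 up, 19 down). The count became 1364, 1741, 325 and 344 without heat-shocked replicates 1 to 4, 455 within series 20 and 3685 within series 21.

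The 3 subunits changed at overlapping bins. At 12 bins all 3 rose and at 7 all 3 fell, of 3482 tested in all 3, and none of the calls shared by 2 subunits went opposite ways. The deeper MglB pair, of 2726977 and 121305 tags, moved the same way at 11 of the 12 rises and at all 7 falls. It was higher after heat shock at 32.4% and lower at 67.6% of the 3482 bins. A change of the background at these bins was thus not told apart from one of the polymerase. The shared rises were 13001, 13501, 494501, 495501, 577501, 772001, 773001, 773501, 774001, 3773001, 3773501 and 4375501, and the shared falls 446001, 447001, 447501, 448001, 2308501, 2309501 and 2399501. At 13001 RpoA went from 76.7 ± 8.17 to 490 ± 192, RpoB from 61.1 ± 33.1 to 616 ± 178 and RpoC from 50.9 ± 17.3 to 604 ± 293 CPM, and the deeper MglB pair from 114 to 1105. At 577501 the subunits rose to 135, 138 and 74.3 from 44.7, 27.7 and 17.9, and MglB held 50.2 and 82.4. At 447001 they fell from 203 ± 71.0, 200.3 ± 58.0 and 291 ± 40.1 to 18.5 ± 17.6, 39.6 ± 8.42 and 32.7 ± 37.8, and the deeper MglB pair went from 287 to 0. RpoA and RpoB shared 12 rises and 9 falls where independent lists give 0.31 and 0.18, RpoA and RpoC 40 and 30 against 4.76 and 7.62, and RpoB and RpoC 19 and 12 against 1.3 and 1.82. Across bins, which are not independent replicates, the log2 changes had Pearson r of 0.492 for RpoA and RpoB (Spearman 0.304, 3976 bins), 0.223 for RpoA and RpoC (0.085, 3485 bins) and 0.546 for RpoB and RpoC (0.454, 4626 bins). After thinning r was 0.666, 0.679 and 0.881. It fell to 0.300 and 0.0378 for RpoA with RpoB and with RpoC without heat-shocked RpoA replicate 1, and to 0.356 for RpoB and RpoC without heat-shocked RpoB replicate 3.

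**Figure D4:**
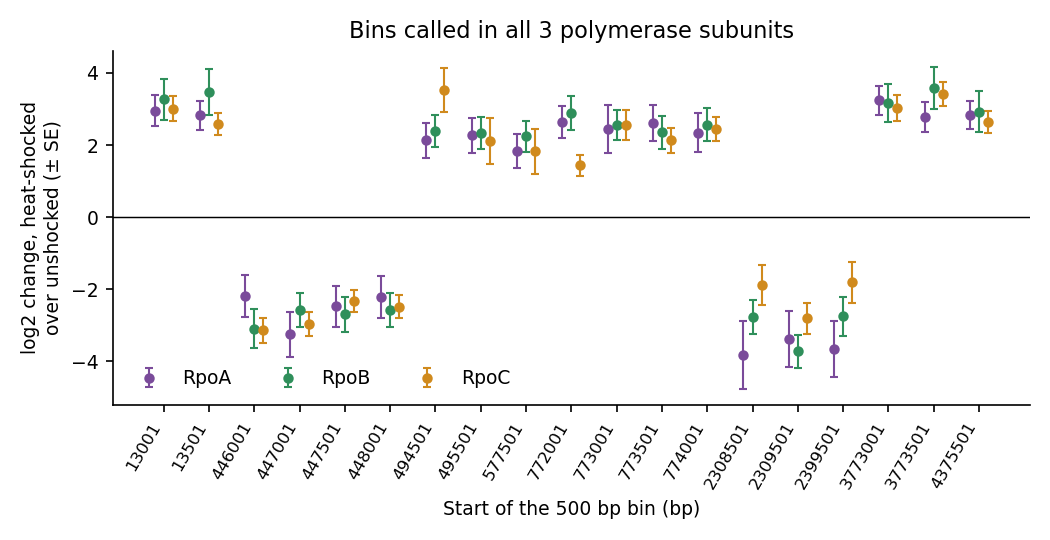
Log2 heat shock change with SE of RpoA, RpoB and RpoC at the 19 bins called in all 3, by the start of the bin. At 12 bins all 3 points lie above 0 and at 7 all 3 lie below it.

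Of the RpoC rises, 23 lay within 20 kb of the nearly empty stretch from 793001 to 806000, 16 below it and 7 above it. The median log2 change over these bins was 2.56 in RpoC and 2.46 in RpoB, of which 4 of 22 tested RpoB bins passed its own test. It was 1.16 in RpoA (3 of 9 passed) and 0.52 in RpoH (2 of 12 passed). The 3 passing RpoA bins, and the passing RpoB bins except 808501, lay at 773001 to 774500, at the far end of the 20 kb reach. From 785001 upward the RpoA bins tested, at 785001, 786501, 787001, 787501 and 792001, changed by −0.582, −0.65, −0.501, 0.26 and 1.16. None of those passed. RpoD, Fis and HimD had medians of 0.15, 0.01 and 0.18 over 18, 20 and 17 tested bins, and 0 of them passed the edgeR test. In the 7 bins above the stretch RpoC held a mean of 12.2 to 19.5 CPM per bin in the unshocked libraries and 232 to 571 in the heat-shocked ones. RpoB held 17.6 to 31.8 and 141 to 381 there. Most of the RpoB bins were high mainly in heat-shocked replicate 1: at 791501 its libraries held 407, 6.56 and 4.73 CPM after heat shock and 32.3, 2.27 and 4.74 without, and over the 16 bins below the stretch 311, 90.5 and 89.2 after heat shock. All 3 heat-shocked RpoB libraries were high at 773001 to 775000 (164 to 326 CPM) and at 808501 to 809500 (279 to 654 CPM). Heat-shocked RpoA libraries differed among themselves, with 233, 0 and 3.73 CPM per bin. The deeper MglB pair held 48.8 without shock and 435 after it.

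**Figure D5:**
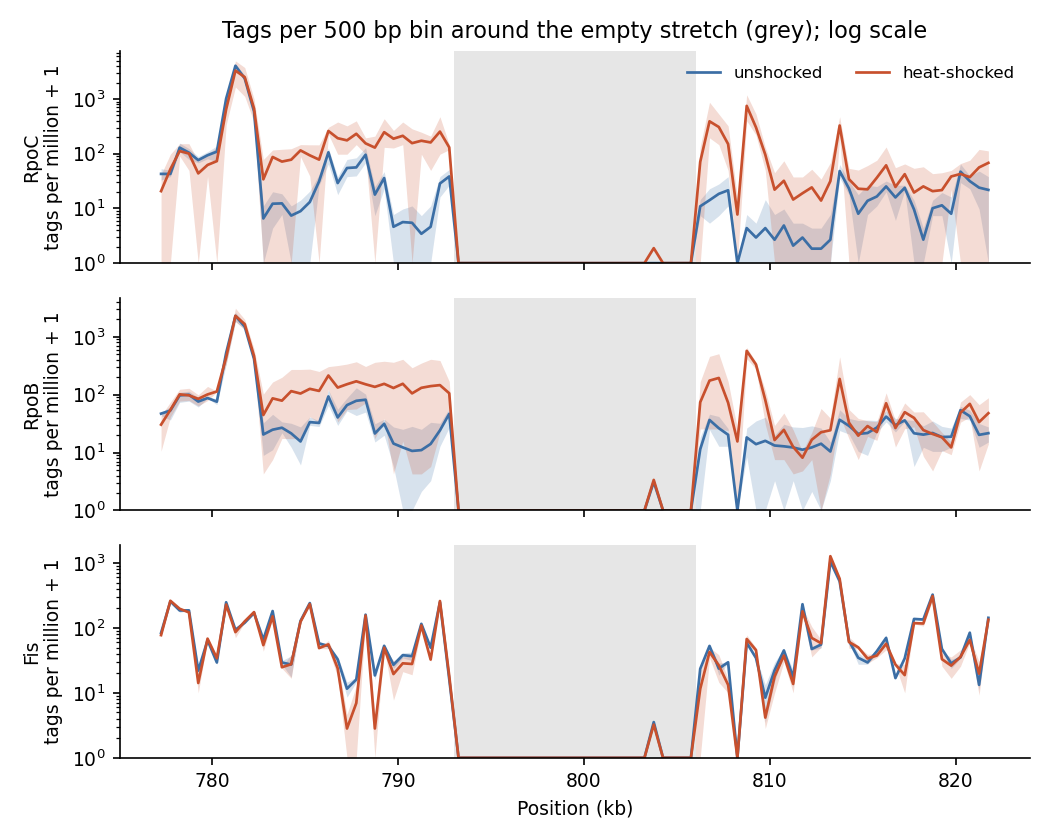
CPM plus 1 (log axis) per 500 bp bin by position in kb around the nearly empty stretch from 793001 to 806000 (grey) for RpoC, RpoB and Fis, with lines for the means of unshocked and heat-shocked libraries and bands from the lowest to the highest library. In RpoC and RpoB the heat-shocked mean lies above the unshocked one in the bins next to the stretch on both sides, with a wide band in RpoB where 1 library largely sets the mean, and in Fis the 2 lines run close together.

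RpoD, RpoN, Fis, HimD and MglB had 0 bins past the threshold in the edgeR heat shock test. With the library series as a block, Fis had 25 calls (23 up, 2 down), and its 2 pairs passed the 0.1 of the pairing check, at 0.219. HimD had 13 (9 up, 4 down) with a series term. At an unadjusted p under 0.05 there were 772 of 7423 bins for RpoD, 33 of 468 for RpoN, 265 of 8852 for Fis, 296 of 7181 for HimD and 7 of 1105 for MglB, and DESeq2 called 116, 0, 0, 3 and 0. The 897 RpoD bins of the site rule held 50.2% ± 8.14 of RpoD tags without shock and 55.3% ± 3.44 after it (n = 2 and 2), the 1482 Fis bins 50.4% ± 2.18 and 53.5% ± 3.28 (n = 2 and 2), and the 1721 HimD bins 62.6% ± 0.415 and 63.1% ± 6.71 (n = 3 and 3), with exact permutation p of 0.667, 0.667 and 1.0, in designs whose smallest possible p is 0.333, 0.333 and 0.1. Tests on simulated data recovered 64.9% of 2-fold and 94.4% of 4-fold changes for Fis, 45.5% and 93.8% for HimD, 5.6% and 41.9% for RpoD, 23.5% and 73% for RpoN and none for MglB up to 8-fold, so that changes of 4-fold would mostly have been seen in Fis and HimD and changes in MglB were not detectable at this depth. Leaving out 1 library of RpoD, RpoN, Fis or MglB leaves a condition with a lone library, whose spread is assumed to be that of the other condition. It gave 500 and 525 calls without unshocked RpoD replicates 1 and 2 and 62 and 48 without heat-shocked replicates 1 and 2, 153 without heat-shocked Fis replicate 2, 2 without unshocked MglB replicate 1, and 2, 11 and 1 without unshocked RpoN replicates 1 and 2 and heat-shocked replicate 1. HimD, with 3 libraries per condition, had 7 calls without heat-shocked replicate 3. The RpoD calls were 227 (97 up, 130 down) with total tags as the library size and 123 (56 up, 67 down) without the filter on low counts, and the HimD calls 3 within series 20. RpoD also had 45 calls (41 up, 4 down) in wider bins and 10, all down, in 1 fit over all libraries. Peaks of at least 5 tags gave 49 RpoN calls, all down.

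Whether RpoH responded unlike the other proteins was tested as the difference of heat shock changes. RpoH and RpoD differed at 5 of 8960 bins. RpoH changed more at 415001, 1669001 and 4062501 by log2 4.62 ± 1.06, 5.98 ± 1.11 and 4.54 ± 0.96 (SE, edgeR adjusted p 0.0297, 0.00097 and 0.0147) and at 1445001, where neither heat-shocked RpoD library had a listed tag, and less at 1812501 by −3.55 ± 0.81. At 415001 and 1669001 1 of the 2 heat-shocked RpoD libraries had no listed tag. RpoH and RpoA differed at 1 of 7573 bins, 4327001, where RpoA had no listed tag after heat shock. RpoH and RpoB differed at 0 of 9038 in edgeR, with 314 at an unadjusted p under 0.05, and DESeq2 was not run on differences. RpoH and RpoC differed at 1592 of 8957, with RpoH changing more upward at 649 and less at 943. That split depended on the setting, with 76 and 4331 for total tags, 143 and 31 for the replicate block and 0 and 442 for peaks of at least 5 tags. With the replicate block these counts were 0, 0, 0 and 174. Without 1 library the RpoD count became 22 and 3 (unshocked RpoD replicates 1 and 2), 0 and 2 (heat-shocked RpoD replicates 1 and 2), 3 and 28 (unshocked RpoH replicates 1 and 2) and 2, 0, 3 and 0 (heat-shocked RpoH replicates 1 to 4). The RpoA count became 39 and 0 without unshocked RpoA replicates 1 and 2, 2, 0 and 0 without heat-shocked RpoA replicates 1 to 3, and 0 without unshocked RpoH replicate 4 or heat-shocked RpoH replicate 1 or 2. The RpoB count became 3 and 1 without unshocked RpoB replicates 1 and 3 and 1 without heat-shocked replicate 3. The RpoC count became 917 without unshocked RpoC replicate 2 and 2601, 537 and 622 without heat-shocked RpoC replicates 2, 3 and 4.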

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

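All tests of explanations in this part were chosen after the results they bear on had been seen.

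In groups of 4 libraries, a library whose gap to the nearest other, as a share of the group's range, exceeded Dixon's critical value was singled out, which chance does in about 1 in 20 groups, or 4.0 of the 80 tested; 9 were found. RpoH heat-shocked replicate 4 held 3190 CPM at 1914001 against a median of 804.5, and replicate 1 held 22.4 at 2709001 against 0. Unshocked RpoC replicate 4 had the lowest share of tags at RpoH sites, 0.325%, and held 13.5 CPM at 809501 against 0. Heat-shocked RpoC replicate 2 held 530.2 at 809001, 378.8 at 790001 and 871 at 806501 against medians of 229.6, 161.2 and 247.9, and 0 at 449501 against 84.3. Heat-shocked RpoC replicate 1 held 48.5 at 791501 against 191.1.

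The heat shock change of RpoH differed from that of RpoD at 5 bins, of RpoA at 1 bin and of RpoC at 1592 bins, by an interaction term. Of 40 regroupings drawn, as many calls as the real grouping came from 25 for RpoA, with up to 159 calls, from 40 for RpoB, with up to 54, and from 1 for RpoC, the real one, with 811 the most in the others. For RpoB the real grouping gave 0 calls, so every regrouping gave as many and nothing is decided. The regroupings mixed the conditions within both proteins and so removed every heat shock change along with the difference. RpoC alone changed at 799 bins, so the real grouping could stand out without a difference from RpoH. Chance is thus not excluded for that difference in any of these 3. Of the splits of the heat shock comparisons, the real one gave 37 calls for RpoH and 799 for RpoC. The highest other of 35 gave 12 and 200, which argues against a chance split of these libraries. RpoA and RpoB gave 120 and 37 calls with 0 as the highest other, and HimD 0 calls with 1 as the highest other and 10 splits with as many. Their 10 splits are too few for a share under 0.05, and with 0 real calls every HimD split had to give as many.

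RpoC and the deeper MglB pair were higher after heat shock beside the nearly empty stretch from 793001 to 806000, and RpoB was so mainly in heat-shocked replicate 1 outside 773001 to 775000 and 808501 to 809500. Depth is argued against, because with equal tags in listed peaks per library the mean RpoC share over the 23 bins went from 0.008% ± 0.007 to 0.456% ± 0.239 (ratio 53.7, uncertain over so low an unshocked share), a test chosen after a first version, the share of bins separated after thinning, had given an undecided 52.2%. Thinning drops small peaks, so the size of that ratio is not an estimate of the change. Without thinning, in the series 21 libraries of 546440 to 593506 tags, RpoC held 232 and 234 CPM per bin above the stretch after heat shock and 19.5 and 17.1 without, and in series 20 it held 288 and 571 against 12.3 and 12.2. Series is argued against as the whole cause, with 95.7% of the bins separated within both series against 39.1% of all RpoC rises, although of the rises called within 1 series 90.5% (from series 20) and 56.2% (from series 21) were separated in the other, and in peaks of at least 5 tags the rise rested on series 21. More copies of the region are argued against as the whole cause by the larger of the Fis and HimD medians, 0.18 on the log2 scale against 2.56 in RpoC, while capture with the background stays open: the deeper MglB pair rose by a median of 2.71, which may also come from heat-induced transcription of the region carrying polymerase and background alike, and only 1 MglB pair had the depth to show it.

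The share of tags at the 38 RpoH bins was higher after heat shock in RpoC and, within the spread, in RpoH. In RpoC, series is argued against as the whole cause, the lower within-series ratio being 1.5. The thinned ratio was 3.43, but thinning drops small peaks and raised the ratio at the other site sets too. Its size is thus not an estimate of the change. Without thinning, the series 21 libraries of 546440 to 593506 tags gave a ratio of 2.04. This argues against depth as the whole cause, from 2 libraries per condition. From peaks of at least 5 tags the conditions overlapped (exact permutation p = 0.4), thinned RpoC ratios at HimD, RpoN, Fis and RpoD bins were 2.83, 2.10, 1.98 and 0.976, and the MglB ratio of 1.33 leaves a share of background open. In RpoH the thinned ratio of 1.77 (exact permutation p = 0.1143), the MglB ratio and the within-series ratio of 1.63 decide none of depth, background and series, so these cannot be told apart from the shock. A response of RpoH to the shock was not tested apart from them.

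3 stretches of the coordinate range were almost without tags in all 50 libraries, 275001 to 371500, 793001 to 806000 and 1198001 to 1212500, with 180 of 193, 25 of 26 and 27 of 29 bins at 0. Few tags in the libraries are argued against: 0.0% of the 9045 bins outside held no tag, the fewest there being 60, a test chosen after another had been judged unsuitable. Deletions carried by the strain may account for the stretches, since the deepest MglB library held at most 1.81% of the tags that its mean bin predicts. Repeated sequence to which no read could be assigned stays open, as no genome of this build was used here. No biological explanation was tested.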

How the results depend on the processing

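Wider bins, a series term, the 2 shallowest heat-shocked RpoH libraries left out, all 4 MglB libraries as the control, and all alternatives for the interactions, subunit correlations, site shares and set tests were chosen after the data were examined. The planned 150 bp window, gene start, gene list, motif and tagged gene results were not run for want of a matching build, and the planned 500 bp bins became the main analysis. Over all settings 872 of 1110 values of named heat shock bins kept their side of the threshold, 238 did not and 0 reversed. Bins not tested in a setting are left out of these numbers, which therefore favour the bins that remained. Of 74 named bins 41 were tested after thinning, and 28 of them kept it. With peaks of at least 5 tags 28 were tested and 10 kept it. Of 174 values over MglB 143 kept it, 31 did not and 0 reversed. The ratio of unshocked to heat-shocked tags was largest in MglB (21.8), RpoN (11.8) and RpoH (4.84), and in simulated data the share of 4-fold changes recovered did not follow it, with 0 in MglB, 73% in RpoN, 72.5% in RpoH, 41.9% in RpoD and 34.4% in RpoB. The cause of each shift was not tested except where fewer libraries or tags were used by construction.

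Counts of heat shock calls were as follows. DESeq2 gave 101 (98 up) in RpoH, 116 in RpoD, 134 in RpoB, 299 (237 up, 62 down) in RpoC and 3 in HimD. One fit over all libraries gave 12 in RpoH, 10 in RpoD, 56 in RpoA, 262 in RpoB, 2475 in RpoC and 2 in MglB. Thinned libraries gave 5, 44 (31 up, 13 down), 86 (52 up, 34 down), 1, 1 and 1 in RpoH, RpoA, RpoC, Fis, HimD and MglB. Peaks of at least 5 tags gave 0 in RpoH, 49 (all down) in RpoN, 64 (9 up, 55 down) in RpoA, 9 in RpoB and 24 in RpoC. Total tags gave 227 in RpoD, 74 in RpoB and 397 in RpoC, and DESeq2 size factors 460 in RpoC. No filter gave 123 in RpoD and 2321 in RpoC. The replicate block gave 258 in RpoA, 229 (109 up, 120 down) in RpoB, 336 (89 up, 247 down) in RpoC and 25 (23 up, 2 down) in Fis, blocked by series. The blocks of RpoB and RpoC were not shown to pair the libraries, and that of Fis passed the pairing check (0.219). No other such count changed by over 1.5 times. Wider bins gave 45 in RpoD, 23 in RpoB and 506 in RpoC. Series 17 alone gave 0 in RpoH and RpoB, series 21 alone 67 in RpoH and 3685 in RpoC, and series 20 alone 455 in RpoC and 3 in HimD. A series term gave 13 (9 up, 4 down) in HimD, and RpoH without its 2 shallowest heat-shocked libraries 5.

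Counts over MglB were 661, 91, 86, 8 and 152 in RpoH, RpoD, RpoN, RpoB and RpoC with total tags, 7, 304, 163, 0, 635 and 1725 in RpoH, RpoD, RpoN, RpoA, Fis and HimD with DESeq2, 0, 2, 2 and 139 in RpoH, RpoN, RpoA and RpoC with peaks of at least 5 tags, 1 and 935 in RpoA and RpoC with no filter, and 0, 43, 0, 0, 0 and 1655 in RpoH, RpoN, RpoA, RpoC, Fis and HimD over all 4 MglB libraries. Interactions were 23 against RpoD and 4407 (76 up, 4331 down) against RpoC with total tags, 0, 0 and 174 (143 up, 31 down) against RpoD, RpoA and RpoC with the replicate block, and 0, 2, 5 and 442 (all down) against RpoD, RpoA, RpoB and RpoC with peaks of at least 5 tags. Thinned correlations were 0.679 for RpoA and RpoC and 0.881 for RpoB and RpoC. The RpoN share difference turned to −3.62 when thinned. In RpoA's own heat shock comparison the block ended no call of a named bin or set test. In the difference of RpoH and RpoA it took the count from 1 to 0. Camera with an estimated correlation gave adjusted p of 0.150, 0.350 and 0.0673 in RpoA, RpoB and RpoC.

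Leaving out 1 library gave 15 to 75 heat shock calls in RpoH, 48 to 525 in RpoD, 0 to 11 in RpoN, 15 to 239 in RpoA, 0 to 58 in RpoB, 325 to 1741 in RpoC, 0 to 153 in Fis, 0 to 7 in HimD and 0 to 2 in MglB. Over MglB it gave 0 to 770 in RpoH, 0 to 400 in RpoD, 0 to 427 in RpoN, 0 to 184 in RpoA, 0 in RpoB, 1 to 1718 in RpoC, 0 to 3232 in Fis and 0 to 3240 in HimD. Interactions ranged from 0 to 28, 0 to 39, 0 to 3 and 537 to 2601 against RpoD, RpoA, RpoB and RpoC.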

Other observations

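The bins described here were chosen after their values were seen. RpoC levels differed between the largest RpoN sites. At 1403501 to 1404000 and 1564501 to 1565000 RpoN held 4815 ± 1234 and 4925 ± 1596 CPM without shock (SD, n = 2) and RpoC 0.84 ± 1.68 and 2.95 ± 5.9 (n = 4), and at 3578501 and 2690001 RpoN held 15171 ± 7363 and 18686 ± 10693 and RpoC 113.6 ± 21.4 and 87.0 ± 49.4. No test was made between these sites. Opposite-strand tallest peaks lay 157 bp apart at 2849001 and −28.5 bp at 2690001, against 30 to 51.5 bp at the other 8.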
